A study of Mus musculus with 25 samples.

How the data were processed

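Polyadenylated RNA was measured by 3′-end messenger RNA sequencing in 25 mouse samples, 14 of whole choroid plexus and 11 of myeloid cells sorted from the brain. In this kind of library each transcript is read near its 3′ end, so that the count of a gene does not grow with its length. Mice were perfused with saline before the tissue was taken, per the labels. The submitters' processing notes name the aligner Bowtie2, the HOMER software and the genome build mm9. Their versions, the annotation, any trimming and any treatment of duplicate reads are not given in the sources used here. No genome of that build was used, so genes are given by the symbols and RefSeq transcript identifiers of the deposited tables and no coordinates are printed.

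The authors deposited a table of counts per gene for the choroid plexus and another for the sorted cells, each with 19762 genes, and these counts are whole numbers that were not normalized. They also deposited a table for each tissue with a signal per gene scaled to the same number of reads in every library, which holds whole reads divided by a factor per library. Within 0.05 reads, 100% of the scaled values came out as whole reads. In the choroid plexus 99.8% of the genes had equal counts in both kinds of table, taking the first library of the anti-PD-1 group. In the sorted cells the scaled table held 1.24 to 1.42 times as many reads as the count table, and between 56.6% and 69.1% of the genes had equal counts. The difference was large for some abundant transcripts and small for others. S100a8 had 93 counts over the 11 libraries in the count table and 12167 reads in the scaled table, Camp 5 and 12413, S100a9 2591 and 23105, Apoe 3010 and 19783, but Ngp 14926 and 15473. Among the 100 most abundant genes, 98 had counts above 0, with a median ratio of reads to counts of 1.15, and the median over the 6621 genes with at least 100 and fewer than 1000 reads was 1.07. Which step of the processing by the authors made this difference is not given in the sources used here, so levels of abundant transcripts in the sorted cells are uncertain in the count table, and the tests were repeated on the reads recovered from the scaled table.

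Library totals ran from 931461 to 1840072 counts in the choroid plexus and from 343439 to 974777 in the sorted cells. A gene with 0 counts in a library could still be present at up to 3 counts, which is 1.63 to 3.22 CPM in the choroid plexus and 3.08 to 8.74 CPM in the sorted cells. No molecular identifiers are described, so this limit covers counting error only. No fold is given where a group lay at or under that limit, and levels are given in its place.

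The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter by group and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The 14 choroid plexus samples went into 1 fit with a mean per group and the letter M or F of the sample titles as a covariate, which left 10 residual degrees of freedom, 9513 tested genes and a biological coefficient of variation of 0.146. The 11 sorted samples went into another fit with a mean for each of the 4 groups, which left 7 residual degrees of freedom, 9058 tested genes and a biological coefficient of variation of 0.225. The gate comparison took the mean of the D7 and D14 differences. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are mean CPM with TMM factors ± SD over the libraries of a group, and list levels are means of log2 CPM with a prior count of 2.

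Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data and with the rotation test fry. Camera compares a list with all other genes, and fry asks whether its genes move, on balance, in one direction. The lists, 37 in number, were interferon-gamma response, type I interferon response, MHC class I, MHC class II, leukocyte trafficking, TNF and NF-κB response, immediate early genes, choroid plexus epithelium, ependyma and cilia, neuron, astrocyte, oligodendrocyte, endothelium, fibroblast, pericyte and smooth muscle, microglia, disease-associated microglia, border macrophage, monocyte, general macrophage, dendritic cell, neutrophil, T and NK cell, B cell, erythroid, cell cycle, phagocytosis, lysosome, lipid and cholesterol, anti-inflammatory repair, complement, ribosomal protein, oxidative phosphorylation, heat shock and unfolded protein, circadian clock, glucocorticoid response and the PD-1 axis. Another list held genes that check the letter in the titles. A list was tested where at least 5 of its genes were. In the choroid plexus 34 lists were tested, and the neutrophil, T and NK cell and B cell lists had too few tested genes. In the sorted cells 32 lists were tested, and the ependyma, astrocyte, pericyte, B cell and erythroid lists had too few. The lists were written from general knowledge, and many share members. Of the 31 tested interferon-gamma genes in the choroid plexus, 6 were also in the MHC class II list, 6 in the MHC class I list, 2 in the disease-associated microglia list and 0 in the macrophage list.

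Groups, designs, lists, other settings and the rule for named genes were fixed before the data were examined. By that rule, the text names per comparison the 12 called genes with the largest positive and the 12 with the largest negative log2 fold change among those with an average log2 CPM of at least 4. Where fewer than 10 genes were called, it names each of them and the 6 genes of lowest p. It may also name up to 4 members of a list with the lowest p and an average log2 CPM of at least 2, every tested member of the PD-1 axis list and the genes that check the title letter. Not every gene that the rule selects is described, and genes named outside the rule are said to be so.

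The other settings fixed then were DESeq2 1.42.0, size factors of DESeq2 or upper-quartile factors in edgeR, no expression filter, a filter of at least 20 counts, only the compared groups in the fit, other covariates, the replicate number or the leading number of the titles as a block, limma on the log2 of the scaled values with a pseudocount of 1, and leaving out each library in turn. Settings with a cell type index as a covariate, with the reads recovered from the scaled tables, and within a title letter were chosen after the data were seen. Each index is the mean level of marker genes per library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

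The tests were tried on simulated counts with the spread and library sizes of these samples. Each gene was set to its mean over all libraries of the tissue, so the sorted cells pooled both gates. Genes were drawn independently, with 93 to 100 tested genes changed at each fold and the interferon-gamma list raised by 0.5 on the log2 scale. Recovery is therefore not at the levels of 1 gate, and may be lower where fewer genes change. In anti-PD-1 against IgG, with 9352 simulated genes tested, 84.8% of genes changed 2-fold and 100% of those changed 4-fold were recovered. In anti-PD-1 against untreated, with 9376 genes, these shares were 76% and 95.9%, and in IgG against untreated, with 9353 genes, 65.3% and 98%. Between the gates, with 8554 genes, they were 54.8% and 90.4%. Between D14 and D7 they were 34.7% and 75% in the CD45low gate, with 8537 genes, and 13.4% and 67.4% in the CD45high gate, with 8595 genes. No library repeated another: within groups, the chi-square of the counts of 2 libraries per degree of freedom lay between 2.23 and 4.93.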

Results

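Gene expression was measured in 5XFAD mice, a transgenic strain that models Alzheimer's disease and forms amyloid deposits in the brain. The series asks how the brain responds when PD-1, an inhibitory receptor of T cells, is blocked with an antibody. Of the 25 samples, 14 were whole choroid plexus, the epithelial tissue of the brain ventricles that makes cerebrospinal fluid and lies between blood and brain. They came from 5 mice given anti-PD-1, 5 given a control IgG and 4 left untreated. The other 11 were CD11b-positive myeloid cells sorted from brains after PD-1 blockade. A gate of low CD45 served as the microglia gate (n = 3 at D7 and n = 3 at D14), and a gate of high CD45 as that of monocyte-derived macrophages (n = 3 at D7 and n = 2 at D14). The labels do not say what D7 and D14 are counted from, nor whether the sorted libraries came from separate animals. For these, p-values measure only the spread between these libraries, which may be technical. Totals ran from 931461 to 1840072 counts per choroid plexus library and from 343439 to 974777 per sorted library. Ttr, which encodes the thyroid hormone carrier transthyretin of the choroid plexus epithelium, took 10.3% to 16.6% of the choroid plexus counts.

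The titles of the choroid plexus samples carry a letter, M or F, that the labels do not spell out. Genes of the Y chromosome followed it. Ddx3y had 96 to 169 counts in the 7 M libraries and 0 to 4 in the 7 F libraries, Kdm5d 16 to 25 and 0 to 1, Eif2s3y 5 to 14 and 0, and Uty 5 to 17 and 0. Zfy1 and Usp9y had 0 counts in both. The anti-PD-1 and IgG groups each held 2 M and 3 F libraries, and the untreated group 3 M and 1 F. In the first 2 of these groups every M title also ends in the number 14 and every F title in a lower one, so letter and number cannot be told apart there. In the sorted cells the first principal component held 70.6% of the variance and separated the gates.

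Anti-PD-1 was first compared with IgG in the choroid plexus, which asks what the blocking antibody does beyond a control antibody. Transcripts induced by interferon-gamma were higher in the anti-PD-1 libraries than in the IgG libraries. Of 31 tested genes of that list, 25 had a positive estimate and the median log2 fold change was 0.35 (camera, adjusted p = 2.30e-08; adjusted p = 0.172 with an estimated correlation). Adjusted over the list alone 7 genes rose and 1 fell, and over all genes tested 0 did. Igtp, an interferon-inducible GTPase (NM_018738), was at 46.9 ± 17.0 CPM (SD, n = 5) against 24.5 ± 8.05 (n = 5) and 27.2 ± 6.08 in untreated mice (n = 4). Its log2 fold change against IgG was 0.95 ± 0.217 (SE). H2-Ab1, an MHC class II chain, had 0.74 ± 0.210, and Iigp1, another such GTPase, 1.40 ± 0.442. Serping1, which encodes the C1 inhibitor, went the other way at -0.62 ± 0.200. The MHC class II list rose too, with 7 of 8 genes positive, 3 past the threshold adjusted over the list alone and 0 over all genes (adjusted p = 3.15e-04; adjusted p = 0.251 with an estimated correlation). Cd74, the class II invariant chain, had 0.66 ± 0.240 and H2-Eb1 0.64 ± 0.254. General macrophage genes rose, 10 of 11 (adjusted p = 0.00247; adjusted p = 0.485 with an estimated correlation), among them C1qc at 0.78 and Emr1, which encodes F4/80, at 0.93, with 0 past the threshold over the list alone or over all genes.

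Vascular and stromal transcripts were lower with anti-PD-1 than with IgG. The endothelium list fell in 18 of 19 genes (adjusted p = 6.12e-06; adjusted p = 0.172 with an estimated correlation), with Ptprb, an endothelial phosphatase, at -0.74 and Pecam1 at -0.70. The fibroblast list fell in 13 of 14 (adjusted p = 7.44e-06; adjusted p = 0.101 with an estimated correlation), with the matrix genes Dcn at -0.47 and Fn1 at -0.93, the latter with 48.4 CPM in IgG replicate 1 and 14.3 in the next library of that group. The pericyte and smooth muscle list fell in 9 of 11 (adjusted p = 3.16e-04; adjusted p = 0.172 with an estimated correlation), with Rgs5 at -0.68 and Vtn at -0.77. In each of these 3 lists, 0 genes passed over the list alone and 0 over all genes. Lists that fell with larger adjusted p were border macrophage (7 of 9; 0.00596, and adjusted p = 0.210 with an estimated correlation), astrocyte (9 of 11; 0.0107 and 0.172), glucocorticoid response (11 of 16; 0.0107 and 0.373), circadian clock (11 of 17; 0.0209 and 0.172) and TNF response (6 of 9; 0.0454 and 0.251). Of the clock genes, 3 fell when adjusted over the list alone and 0 over all genes: Tef at -0.83 ± 0.199, Dbp at -1.08 ± 0.313 and Bhlhe41 at -0.77 ± 0.226. The glucocorticoid list held Tsc22d3 at -0.53. Lists that rose with larger adjusted p were erythroid (8 of 8; 0.0116, and adjusted p = 0.485 with an estimated correlation), MHC class I (10 of 14; 0.0326 and 0.172) and type I interferon (9 of 13; 0.0454 and 0.485). In the border macrophage, astrocyte, glucocorticoid, TNF, MHC class I and type I lists 0 genes passed over the list alone. The erythroid list had 2 genes past the threshold over the list alone, and Hbb-bt was at 15 ± 18.6 CPM against 3.03 ± 1.41. Globin genes share reads with near-identical copies, so their single values are uncertain.

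The comparison was repeated within each title letter. Among F libraries alone the interferon-gamma list had 27 of 31 genes positive with a median of 0.63 (adjusted p = 2.20e-15), MHC class II 8 of 8 with 0.84 (3.39e-12) and macrophage 11 of 11 with 0.71 (2.13e-09). Among M libraries alone the interferon-gamma list had 17 of 31 positive with a median of 0.08 (adjusted p = 0.701), while MHC class II had 3 of 8 (0.566) and macrophage 4 of 11 (0.191), both with a negative median. The vascular and stromal lists were lower in both, with adjusted p in F and in M of 1.35e-04 and 0.00743 for endothelium, 5.32e-04 and 0.00170 for fibroblast, and 0.0165 and 0.00170 for pericyte. In M this rested largely on IgG replicate 1 for fibroblast, and on both IgG replicate 1 and anti-PD-1 replicate 1 for endothelium and pericyte. Replicate 1 is the first of each pair of values here. The mean log2 CPM of the IgG M libraries was 6.82 and 6.09 for fibroblast, 5.40 and 4.76 for endothelium and 4.79 and 4.11 for pericyte. With anti-PD-1 it was 5.99 and 6.13, 4.35 and 5.02, and 3.59 and 4.24. For the other lists called in all libraries the adjusted p in F and in M were 0.00558 and 0.292 for border macrophage, 0.0490 and 0.170 for astrocyte, 0.0836 and 0.0316 for glucocorticoid, 0.0165 and 0.420 for clock, 0.280 and 0.133 for TNF, 0.0165 and 0.304 for erythroid, 0.0534 and 0.279 for MHC class I, and 0.0534 and 0.292 for type I. Lists called only within a letter were, in M, choroid plexus epithelium (up, 0.00170), complement (down, 0.00170), oxidative phosphorylation (up, 0.0368) and monocyte (down, 0.0395), and in F heat shock and unfolded protein (down, 0.0117). With an estimated correlation none of the within-letter list calls held, with a smallest adjusted p of 0.214 in F and 0.524 in M. A direct test of F minus M gave a median difference of 0.44 for interferon-gamma (adjusted p = 1.16e-04), 0.87 for MHC class II (2.41e-04) and 0.89 for macrophage (1.80e-05), each with adjusted p = 0.535 with an estimated correlation. In it edgeR called 0 of 9513 genes, and 313 had an unadjusted p under 0.05. All of these tests were chosen after the data were seen.

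**Figure D1:**
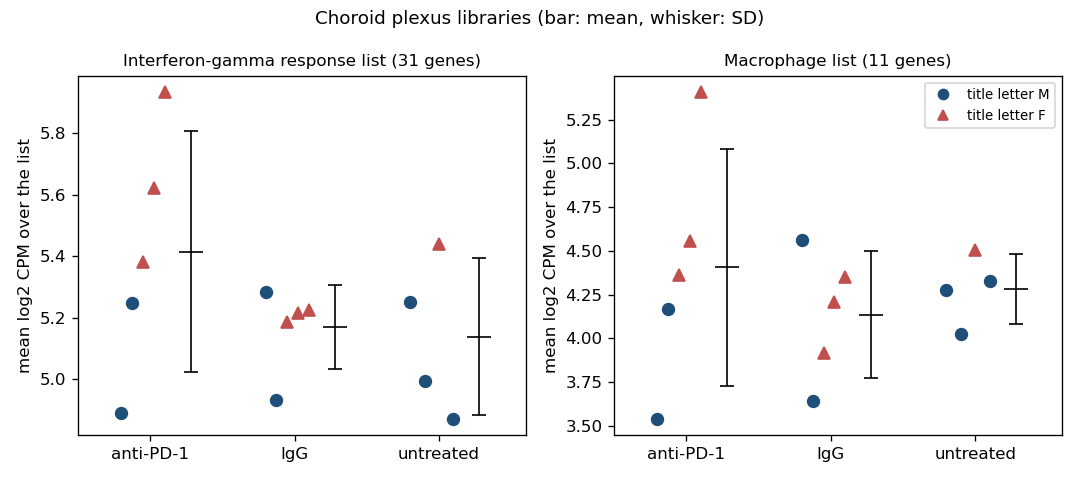
Mean log2 CPM over the interferon-gamma list (left, 31 genes) and the general macrophage list (right, 11 genes) in each choroid plexus library, by group on the horizontal axis; circles are libraries with the title letter M, triangles those with F, and the bar and whisker beside them the mean and SD of the group. On the left the 3 F libraries of the anti-PD-1 group lie between 5.38 and 5.93 and the F libraries of the IgG group between 5.19 and 5.23, while the M libraries of these groups lie between 4.89 and 5.28.

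No single gene passed the threshold over all genes between anti-PD-1 and IgG. With edgeR 0 of 9513 genes were called, 442 had an unadjusted p under 0.05, and DESeq2 called 1. Among the genes of lowest p were Ppap2b at -0.73 ± 0.159, Igtp, Osmr, the oncostatin M receptor, at -1.5 ± 0.346, Tef, and Pla2g4a, a phospholipase A2, at -1.12 ± 0.278. Of the PD-1 axis list, which did not pass, Ifngr1 had -0.34, Ifngr2 -0.27, Jak1 -0.08 and Jak2 0.08, none of them called. Without IgG replicate 5 edgeR called 2 genes, Tef among them, and within letters it called 0 in F (410 unadjusted) and 1 in M (357 unadjusted), Pttg1, chosen after its value was seen.

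Leaving out 1 library ended several of the weaker list calls of anti-PD-1 against IgG, and the interferon-gamma, MHC class II, endothelium, fibroblast and pericyte calls were kept under each. Without anti-PD-1 replicate 5 the adjusted p was 0.931 with the opposite direction for erythroid, 0.552 for macrophage, 0.438 for type I, 0.262 for astrocyte, 0.200 for MHC class I, 0.192 for clock and 0.0566 for border macrophage. Without anti-PD-1 replicate 1 it was 0.115 for TNF and 0.0527 for both border macrophage and erythroid. Without replicate 2 it was 0.283 for type I, 0.155 for MHC class I and 0.0771 for TNF. Without replicate 3 it was 0.246 for TNF, and without replicate 4 it was 0.180 for glucocorticoid. Without IgG replicate 5 it was 0.352 for type I, 0.184 for glucocorticoid, 0.168 for astrocyte, 0.0609 for border macrophage, 0.0565 for TNF and erythroid, and 0.0510 for MHC class I. Without IgG replicate 3 it was 0.169 for MHC class I, 0.120 for clock, 0.111 for astrocyte, 0.0935 for TNF and 0.0714 for macrophage. Without IgG replicate 2 it was 0.136 for astrocyte, 0.0967 for type I, 0.0712 for glucocorticoid, 0.0669 for MHC class I and 0.0515 for erythroid. Without IgG replicate 1 it was 0.280 for TNF and 0.237 for astrocyte, and without IgG replicate 4 it was 0.0539 for type I.

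The second comparison set anti-PD-1 against untreated choroid plexus. The interferon-gamma list was higher here as well, with 26 of 31 genes positive and a median of 0.15 (adjusted p = 0.0174; adjusted p = 0.792 with an estimated correlation), and 0 genes passed over the list alone or over all genes. Igtp and the GTPase Tgtp1, which shares reads with its near-identical copy Tgtp2 and is uncertain, both had 0.59. The pericyte and smooth muscle list fell in 10 of 11 genes (adjusted p = 0.0104; adjusted p = 0.792 with an estimated correlation), with Cspg4 at -0.94. Acta2, which encodes smooth muscle actin, had 1.02 in the other direction, and 0 genes passed over the list alone or over all genes. Within M the interferon-gamma list had a camera adjusted p of 0.690 and the pericyte list 0.260. Within F the medians were 0.16 and -0.55, with 1 untreated F library. The spread in F came from the other groups, so list tests there cannot describe untreated F mice. The MHC class II list was also up in F, and the endothelium, lipid and immediate early lists down. The lowest p belonged to Adamts1, a secreted protease, at 125 ± 19.9 CPM against 217 ± 36.2 (-0.77 ± 0.144, adjusted p = 0.123). It was followed by Dct, a melanin synthesis enzyme, at -1.76 ± 0.377, D4Wsu53e at -0.92, the nucleolar gene Npm1 at 0.80, Smarcad1 at 0.90 and Smtn at -1.46. Of the PD-1 axis list, Ifngr1 had -0.03, Ifngr2 -0.15, Jak1 -0.15 and Jak2 -0.07. With edgeR 0 of 9513 genes were called and 368 had an unadjusted p under 0.05. DESeq2 called 2, Adamts1 and Dct, and within M libraries alone edgeR called 1, Pttg1. The interferon-gamma call ended without anti-PD-1 replicate 5 (0.319) or untreated replicates 2 (0.0621), 3 (0.152) or 4 (0.151), and the pericyte call without anti-PD-1 replicate 1 (0.108) or untreated replicate 3 (0.521).

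IgG was then compared with untreated choroid plexus, to show how the control groups differ. Glucocorticoid-responsive genes rose with IgG, 14 of 16 positive with a median of 0.19 (adjusted p = 0.00135; adjusted p = 0.790 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 40.9 ± 13.8 CPM (n = 5) against 14.9 ± 5.88 (n = 4), a log2 fold change of 1.56 ± 0.370, and was the only gene past the threshold adjusted over the list alone, while 0 passed over all genes. Angptl4 had 0.96 and Tsc22d3 0.58. Erythroid genes fell, 8 of 8 (adjusted p = 0.00135; adjusted p = 0.790 with an estimated correlation), as did macrophage genes, 10 of 11 (0.0249; adjusted p = 0.916 with an estimated correlation), with 0 genes of either past the threshold over the list alone or over all genes. This comparison shares its IgG libraries with the first, so opposite signs in the 2 are not independent. Within M the camera adjusted p for glucocorticoid, erythroid and macrophage were 1.78e-04, 0.00165 and 0.688. The first 2 had adjusted p = 0.727 and adjusted p = 0.800 with an estimated correlation. Within F, with 1 untreated library, the medians of these lists were 0.13, -0.61 and -0.33. M alone also called the fibroblast list (up, 0.0470; adjusted p = 0.815 with an estimated correlation). Among the genes of lowest p, Npm1 had 0.96, Cpne2 -0.62, Dct -1.60 and Ceacam16 -1.58, and of the PD-1 axis Ifngr1 had 0.30, Ifngr2 0.11, Jak1 -0.06 and Jak2 -0.15. With edgeR 0 of 9513 genes were called and 471 had an unadjusted p under 0.05. DESeq2 called 2, Npm1 among them. Without IgG replicate 5, untreated replicate 1, or anti-PD-1 replicate 3 or 5, edgeR called 1. The macrophage call ended without IgG replicates 2 (0.264) or 3 (0.176) or untreated replicate 4 (0.167).

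In the sorted cells, the gates were compared to show how monocyte-derived macrophages differ from microglia. Genes of circulating myeloid cells were far higher in the CD45high gate. The monocyte list rose in 37 of 38 genes with a median log2 fold change of 5.18 (adjusted p = 3.83e-50; adjusted p = 0.0397 with an estimated correlation), and 37 rose and 1 fell both over the list alone and over all genes. Fn1 had 6.39 ± 0.229, Cd44, a hyaluronan receptor, 5.56 ± 0.200 and Emb 6.44 ± 0.234. S100a4 was at 349 ± 48.8 CPM at D7 (n = 3) and 292 ± 1.97 at D14 (n = 2) against 3.09 ± 2.91 and 1.03 ± 0.182 in the CD45low gate. Neutrophil genes rose as strongly, 18 of 18 (adjusted p = 1.85e-26; adjusted p = 0.0423 with an estimated correlation), all past the threshold over the list alone and over all genes. Mmp8, neutrophil collagenase (NM_008611), was at 3558 ± 464 CPM at D7 and 2398 ± 32.5 at D14 in the CD45high gate against 19.0 ± 12.0 and 6.83 ± 4.21 in the CD45low gate (8.07 ± 0.261). Cxcr2, a chemokine receptor of neutrophils, had 7.08 and Retnlg 6.08. The levels of S100a4 and Retnlg are uncertain, with 691 and 2192 counts but 3843 and 7836 reads recovered from the scaled values, on which Retnlg had 6.36. The gate named for macrophages thus held neutrophil transcripts at high level. These 2 list calls held with an estimated correlation.

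Cell cycle genes rose in the CD45high gate in 32 of 32, of which 28 were called over all genes and 28 over the list alone (adjusted p = 9.56e-14; adjusted p = 0.186 with an estimated correlation), with Ube2c at 4.71 ± 0.215 and Top2a at 4.03 ± 0.220. Type I interferon genes rose in 36 of 40, with 28 up and 1 down over all genes and 29 up and 1 down over the list alone (4.63e-07; adjusted p = 0.497 with an estimated correlation), among them Samd9l at 4.66 and Cmpk2 at 4.31. Interferon-gamma genes rose in 35 of 41, with 29 up and 4 down over all genes and over the list alone (8.63e-04; adjusted p = 0.368 with an estimated correlation), with Ifitm3 at 4.29, Ifi47 at 4.12 and Cd74 at 2.27. T and NK cell genes rose in 13 of 14, with 13 up and 1 down over all genes and over the list alone (1.44e-04; adjusted p = 0.110 with an estimated correlation), with the chemokine Ccl5 at 4.14. MHC class II genes rose in 11 of 13, with 9 up and 2 down over all genes and 10 up and 2 down over the list alone (0.0126; adjusted p = 0.497 with an estimated correlation). Of the PD-1 axis, Jak2 (0.92), Cd274, which encodes the PD-1 ligand PD-L1 (0.96), and Jak1 (0.60) rose, Havcr2, which encodes TIM-3 (-2.18), and Ifngr1 (-0.54) fell, and Ifngr2 did not pass (-0.04). Cd8a was called as well, at 16.7 ± 13.8 and 57.5 ± 21.6 CPM in the CD45high gate at D7 and D14 against 1.31 ± 0.472 and 0.

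Microglia genes fell in the CD45high gate in 33 of 34 with a median of -2.24, of which 31 were called over all genes and 32 over the list alone (adjusted p = 4.72e-17; adjusted p = 0.368 with an estimated correlation). Rtn4rl1 had -4.16 ± 0.209, Sall1, a transcription factor of microglial identity, -4.07 ± 0.299, and Pmepa1 -2.56 ± 0.177. Among genes with the largest differences, several were near 0 in 1 gate. Clec4e, a C-type lectin of activated myeloid cells, was at 430 ± 80.7 and 509 ± 2.54 CPM in the CD45high gate at D7 and D14 against 1.05 ± 1.07 and 0.725 ± 0.647. Emp1 was at 113 ± 65.2 and 78.5 ± 11.1 against 0, Trem1 at 455 ± 97.9 and 381 ± 42.9 against 5.37 ± 6.6 and 0.619 ± 0.536, and the eosinophil granule gene Prg2 at 273 ± 64.8 and 56.3 ± 38.0 against 1.02 ± 1.00 and 0. The level of Prg2 is uncertain, with 344 counts in the count table and 2173 reads in the scaled table. Fpr1, Asprv1, Clec4d, Mgam, Sirpb1b and 2010002M12Rik were also among the 12 largest increases. On the other side, Tgfa, which encodes transforming growth factor alpha, was at 44.3 ± 4.35 and 52.2 ± 11.1 CPM in the CD45low gate against 1.98 ± 3.43 and 0, Col6a3 at 44.1 ± 26.8 and 44.8 ± 11.9 against 0.990 ± 1.72 and 0, and Zfp354a at 16.1 ± 13.9 and 22.5 ± 7.72 against 0. They were followed by Klf12, Tmem8c, Ninl, Magi1, Zscan18, Gprasp2, Jam3, Mrc2 and Pear1.

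**Figure D2:**
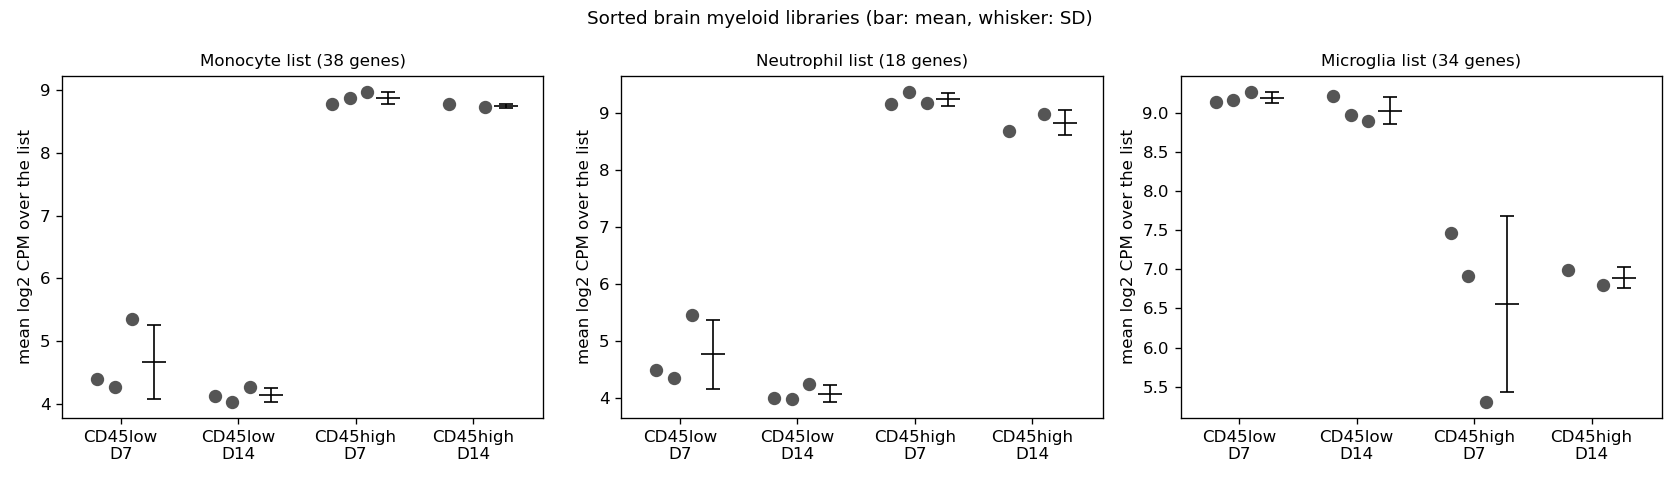
Mean log2 CPM over the monocyte (38 genes), neutrophil (18 genes) and microglia (34 genes) lists in each sorted library, by gate and D label on the horizontal axis; points are libraries, and the bar and whisker beside them the mean and SD of the group. Monocyte levels lie between 8.72 and 8.97 in the CD45high gate and between 4.04 and 5.35 in the CD45low gate, and neutrophil levels between 8.68 and 9.38 and between 3.98 and 5.46; in both lists the highest CD45low library is replicate 3 of D7.

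In all, 4822 of 9058 genes differed between the gates, 2432 higher and 2390 lower in the CD45high gate, and 5271 had an unadjusted p under 0.05. The share of higher calls was 50.4%, against 43.5% with upper-quartile factors and 40.1% with limma on the scaled values. The median of all genes was -0.08 with TMM factors and -0.21 with upper-quartile factors, so small differences between the gates depend on the scaling.

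Within the CD45low gate, D14 was compared with D7 to follow the microglia gate over the labelled times. Of 9058 genes 9 were called, 2 up and 7 down, and 665 had an unadjusted p under 0.05. Enpp2, which encodes autotaxin, rose from 50.5 ± 28.9 to 293 ± 111 CPM (n = 3 each; 2.48 ± 0.361), and the calcium channel gene Cacna1a from 24.8 ± 1.22 to 102 ± 22.7 (2.03 ± 0.326). Genes abundant in neutrophils and monocytes fell, with Anxa1 at -4 ± 0.727, Chil3 at -3.26 ± 0.601, the iron-binding Lcn2 at -3.04 ± 0.546 and lactoferrin, Ltf, at -2.63 ± 0.504, and so did Jdp2 (-1.84 ± 0.286), Pde2a (-1.56 ± 0.291) and Tbc1d9 (-1.46 ± 0.237). Anxa1 and Chil3 were at 273 ± 365 and 539 ± 676 CPM at D7, with most of it in replicate 3. Both were more abundant in the CD45high gate at D7, at 2224 ± 150 and 2946 ± 234 CPM. With the reads recovered from the scaled table the calls of Anxa1, Chil3, Lcn2, Ltf and Tbc1d9 ended (adjusted p = 0.0580 each), as did that of Pde2a (0.0627), and those of Enpp2, Cacna1a and Jdp2 held.

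By lists, type I interferon genes rose in the CD45low gate from D7 to D14, 32 of 40 with a median of 0.65 (adjusted p = 1.71e-08; adjusted p = 0.331 with an estimated correlation), and 1 gene, Rtp4 at 1.28 ± 0.319, passed over the list alone, 0 over all genes. Monocyte genes fell in 31 of 38 (8.57e-07; adjusted p = 0.331 with an estimated correlation), with 5 down over the list alone and 1 over all genes. Neutrophil genes fell in 13 of 18 (8.57e-07; adjusted p = 0.321 with an estimated correlation), with 2 up and 9 down over the list alone and 2 down over all genes. Choroid plexus epithelium genes rose in 10 of 14 (9.46e-07; adjusted p = 0.273 with an estimated correlation), with 4 up over the list alone and 1 over all genes, namely Enpp2, Igfbp2, Igf2 and Ttr, which went from 199 ± 87.3 to 460 ± 100 CPM. These are markers of another tissue that moved with the D label. The level of Ttr is uncertain, with 2017 counts but 7168 reads recovered from the scaled values over the sorted libraries. Glucocorticoid genes fell in 9 of 13 (5.90e-04; adjusted p = 0.321 with an estimated correlation), 5 over the list alone and 1 over all genes, with Fkbp5 at -1.39 and Ddit4 at -1.92. Neuron genes fell in 7 of 7 (0.00159; adjusted p = 0.321 with an estimated correlation), 1 over the list alone and 0 over all genes. TNF genes rose in 15 of 24 (0.00852; adjusted p = 0.424 with an estimated correlation), 2 over the list alone and 0 over all genes, with Tnfaip3 at 1.25 and Cd83 at 0.73. The disease-associated microglia list was called up (0.0294; adjusted p = 0.755 with an estimated correlation) with a mean of 0.30 but a median of -0.07 and 16 of 35 genes positive. In it 5 rose and 1 fell over the list alone and 0 over all genes, with Itgax at 1.73, Csf1 at 1.24 and Axl at 0.95. MHC class II genes fell in 10 of 13 (0.0255; adjusted p = 0.526 with an estimated correlation), 1 over the list alone and 0 over all genes, with H2-DMb1 at -1.86. Macrophage genes fell in 16 of 19 (0.0327; adjusted p = 0.872 with an estimated correlation), 0 over the list alone or over all genes. Of the PD-1 axis, Cd274 (0.11), Ifngr1 (0.12), Ifngr2 (0.21), Jak1 (-0.03), Jak2 (-0.12), Havcr2 (-0.16) and Cd8a (1.31 ± 0.472 CPM at D7 and 0 at D14) did not pass.

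These CD45low counts changed with the libraries used. Without D7 replicate 1 edgeR called 25 genes, without D7 replicate 2 it called 34, without D14 replicate 1 it called 1, and without D14 replicate 2 it called 0, while DESeq2 called 23. Without D7 replicate 3 the adjusted p was 0.773 for macrophage, with the opposite direction, 0.312 for neuron and 0.0910 for MHC class II. Monocyte and neutrophil genes kept their calls without it, but that library stood apart, at a mean log2 CPM of 5.35 against 4.41 and 4.27 in the other D7 libraries for monocyte and 5.46 against 4.48 and 4.35 for neutrophil. Without D7 replicate 1 it was 0.156 for both MHC class II and disease-associated microglia and 0.123 for TNF, and without D7 replicate 2 it was 0.145 for disease-associated microglia. Without D14 replicate 1 it was 0.0789 for disease-associated microglia, without D14 replicate 2 it was 0.255 for TNF and 0.236 for macrophage, and without D14 replicate 3 it was 0.112 for MHC class II and 0.0897 for macrophage. Among single genes, Enpp2 lost its call without D14 replicate 2 (adjusted p = 0.0621) and Pde2a without D7 replicate 2 (0.121). The other 8 called genes lost theirs without D14 replicate 1, at 0.0936 for Jdp2, 0.131 for Anxa1, Tbc1d9 and Cacna1a, 0.190 for Lcn2, 0.196 for Pde2a and 0.202 for Ltf and Chil3. Without D14 replicate 2 the adjusted p was 0.0621 for Tbc1d9 and Cacna1a, 0.142 for Jdp2, 0.391 for Anxa1, Lcn2 and Chil3, and 0.405 for Ltf and Pde2a. Without D14 replicate 3 it was 0.0624 for Tbc1d9, 0.0760 for Ltf, 0.0882 for Lcn2, 0.153 for Chil3 and 0.185 for Anxa1. The genes that lost their calls kept their direction, with Anxa1 at -4.48, Lcn2 at -3.12 and Jdp2 at -1.92 without D14 replicate 1.

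In the CD45high gate interferon transcripts were higher at D14 (n = 2) than at D7 (n = 3). The type I list rose in 35 of 40 genes with a median of 0.91 (adjusted p = 4.20e-16; adjusted p = 0.262 with an estimated correlation), and 16 passed over the list alone and 0 over all genes. Ifit1 was at 150 ± 90.4 against 39.3 ± 19.8 CPM (1.88 ± 0.454), Ifit2 at 108 ± 49.5 against 27.0 ± 12.0 (1.96 ± 0.451), and Phf11d had 1.62 ± 0.362. The interferon-gamma list rose in 33 of 41 (2.68e-05; adjusted p = 0.262 with an estimated correlation), 7 over the list alone and 0 over all genes, with Irgm1 at 1.28 and the chemokine Cxcl10 at 1.84. Neutrophil genes fell in 16 of 18 (0.00184; adjusted p = 0.435 with an estimated correlation), 1 over the list alone and 0 over all genes, with Csf3r at -0.86. T and NK cell genes rose in 12 of 14 (0.0131; adjusted p = 0.262 with an estimated correlation), 0 over the list alone or over all genes. Lipid genes rose in 17 of 25 (0.0131; adjusted p = 0.416 with an estimated correlation), 2 over the list alone and 0 over all genes. The PD-1 axis list rose in 7 of 8 (0.0275; adjusted p = 0.416 with an estimated correlation), 0 over the list alone or over all genes, with Ifngr1 at 0.58, Jak2 at 0.51, Cd274 at 0.68, Havcr2 at 0.38, Jak1 at 0.02, Ifngr2 at -0.14 and Cd8a at 1.86 (16.7 ± 13.8 to 57.5 ± 21.6 CPM). Oligodendrocyte genes fell in 5 of 7 (0.0449; adjusted p = 0.416 with an estimated correlation), 1 over the list alone and 0 over all genes, namely Mbp at -1.46. TNF genes rose in 16 of 24 (0.0452; adjusted p = 0.514 with an estimated correlation), 2 over the list alone and 0 over all genes, with Cd83 at 1.57.

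Of single genes, Ly6a, which encodes the surface antigen Sca-1 and is induced by interferon, was the only one called of 9058 in the CD45high gate. It rose from 25.4 ± 8.90 to 148 CPM (137 and 158 in the 2 libraries) with a log2 fold change of 2.54 ± 0.408 (adjusted p = 0.0469). Of the tested genes 951 had an unadjusted p under 0.05, and DESeq2 called 15. The call ended without D7 replicate 2 (adjusted p = 0.0504) or 3 (0.0993) or D14 replicate 1 (0.413) or 2 (0.0895). Next by p were Cd83, the eosinophil granule genes Prg2 at -2.29 ± 0.404 and Epx at -2.77 ± 0.496, D8Ertd738e at -1.24 and Desi2 at 2.05. On the reads recovered from the scaled values, 6 genes were called, among them Prg2 (adjusted p = 0.0118), Ly6a and Desi2 (0.0265 each), Cd83 (0.0449) and Epx (0.0478). The count of calls was 13 without D7 replicate 1, and 0 without D7 replicate 3 or either D14 replicate. Without D7 replicate 1 the adjusted p was 0.0540 for TNF and for PD-1 axis and 0.106 for oligodendrocyte. Without D7 replicate 3 it was 0.330 for TNF, 0.0549 for lipid, 0.0530 for PD-1 axis and 0.0512 for oligodendrocyte and for T and NK cell. Without D14 replicate 1 it was 0.303 for oligodendrocyte, 0.242 for PD-1 axis, 0.136 for lipid and 0.0638 for neutrophil, and without D14 replicate 2 it was 0.181 for TNF.

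**Figure D3:**
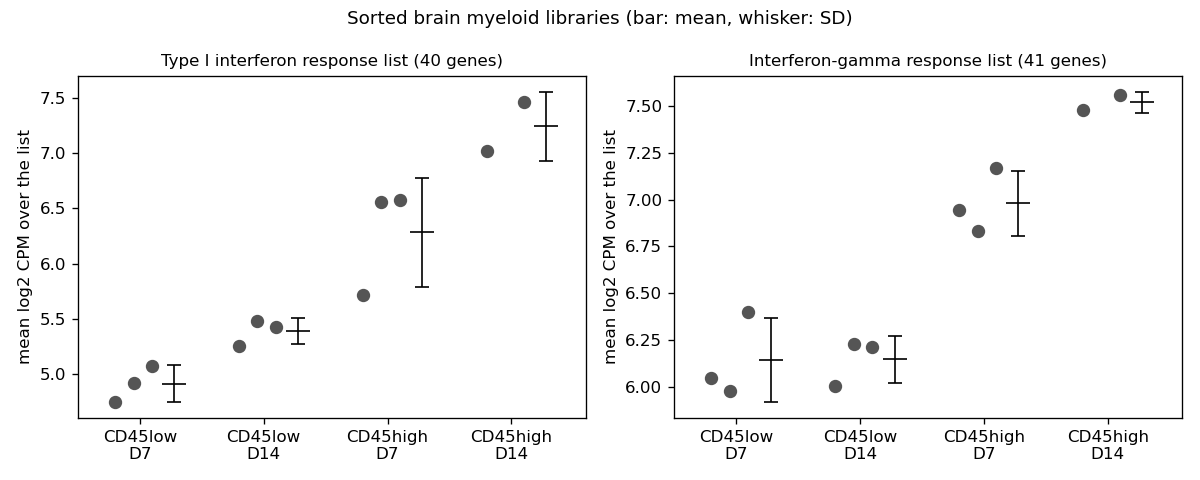
Mean log2 CPM over the type I interferon (40 genes) and interferon-gamma (41 genes) lists in each sorted library, by gate and D label on the horizontal axis; points are libraries, and the bar and whisker beside them the mean and SD of the group. Mean type I levels are 4.91 at D7 and 5.39 at D14 in the CD45low gate, and 6.28 and 7.24 in the CD45high gate.

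The difference between the D14 changes of the 2 gates was tested directly. The change of the interferon-gamma list was more positive in the CD45high gate, with 31 of 41 genes positive and a median difference of 0.42. Its adjusted p was 0.00367 with camera, and adjusted p = 0.815 with an estimated correlation. The mean log2 CPM of this list went from 6.98 to 7.52 in the CD45high gate and from 6.14 to 6.15 in the CD45low gate. The monocyte list differed with 34 of 38 positive and 0.53 (0.00367; adjusted p = 0.815 with an estimated correlation), but did not rise in the CD45high gate: its mean log2 CPM went from 8.87 to 8.75 there and from 4.68 to 4.15 in the CD45low gate. Both lists had 0 genes past the threshold over the list alone or over all genes. The type I list did not pass in this test (adjusted p = 0.105). Lpxn (1.88 ± 0.424), Csf1 (-2.23 ± 0.534), Cacna1a (-2.38 ± 0.585), Slc22a17 (-2.11 ± 0.524) and Arhgef18 (-1.70 ± 0.425) had the lowest p together with Pacsin1, which was at 0 in the CD45high gate at D14 and at 11.7 ± 4.23 CPM at D7. With edgeR 0 of 9058 genes were called, 542 had an unadjusted p under 0.05 and the smallest adjusted p was 0.626. Without CD45low D7 replicate 3 the adjusted p was 0.147 for interferon-gamma and 0.591 for monocyte, and without CD45low D14 replicate 2 it was 0.0530 for monocyte.

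Of 230 list tests over the 7 comparisons 47 passed, of which 2 held with an estimated correlation and 8, all between the gates, held with fry. Lists that passed in none of their comparisons with all libraries were ribosomal protein (smallest adjusted p = 0.0576), heat shock and unfolded protein (0.0627), oxidative phosphorylation (0.0636), dendritic cell (0.0676), phagocytosis (0.0695), lysosome (0.0717), complement (0.142), leukocyte trafficking (0.154), immediate early (0.167), anti-inflammatory repair (0.241) and ependyma and cilia (0.439).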

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

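The tests of F against M, the index covariates, the reads recovered from the scaled table, the splits by title letter and the use of untreated mice against the IgG explanation were chosen after the result was seen.

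Samples far from the others of their group were looked for in 168 groups of values, and 10 were found, where chance gives about 5% of the groups. In untreated replicate 1 Ttr took 16.6% of the counts (next library 13.2) and Smtn was at 12.1 CPM (next 9.82). In untreated replicate 2 Ppap2b was at 171 CPM (next 215), and in untreated replicate 4 Fn1 was at 17.8 (next 11.4). In the IgG group Fn1 was at 48.4 CPM in replicate 1 (next 14.3), Iigp1 at 8.28 in replicate 3 (next 3.73), Angptl4 at 54.2 in replicate 5 (next 23.2), and the mean log2 CPM of the interferon-gamma list at 4.93 in replicate 2 (next 5.19). In anti-PD-1 replicate 5 Ifngr1 was at 30.2 CPM (next 24.8) and Hba-a2, whose reads are shared with its copy Hba-a1, at 34.2 (next 8.44).

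The difference between anti-PD-1 and IgG was itself compared between F and M libraries, after the within-letter values were seen. F minus M, the median was 0.89 for the macrophage list (adjusted p = 1.80e-05), 0.44 for interferon-gamma (1.16e-04), 0.87 for MHC class II (2.41e-04), 0.56 for complement (0.00973), 0.54 for monocyte (0.00989) and -0.13 for choroid plexus epithelium (0.00989). Each of these had adjusted p = 0.535 with an estimated correlation, and 0 of 9513 genes were called in edgeR, with 313 at an unadjusted p under 0.05. F and M differ in the title number as well, so the difference cannot be assigned to either. Between the gates, the D14 minus D7 difference was more positive in CD45high by a median of 0.42 for the interferon-gamma list and 0.53 for the monocyte list (adjusted p = 0.00367 for both; adjusted p = 0.815 with an estimated correlation).

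Signal also stood in genes of the scaled tables that the count tables do not hold. Its share of the scaled total was at most 0.132% in the choroid plexus (lowest 0.0977) and at most 1.94% in the sorted cells (lowest 1.75). There Malat1 was at 2182 ± 158 RPM in CD45low D7 (n = 3), 2008 ± 54.2 in CD45low D14 (n = 3), 1472 ± 246 in CD45high D7 (n = 3) and 910 ± 86.8 in CD45high D14 (n = 2), and Neat1 at 359 ± 59.1, 388 ± 64.3, 556 ± 94.0 and 587 ± 65.8.

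The higher interferon-gamma list in anti-PD-1 than in IgG choroid plexus was weighed against technical and cell composition explanations. A lower share of stromal and vascular cells is argued against, since the median was 0.41 with an index of these cells as a covariate and did not fall from 0.35. Its adjusted p of 1.65e-12 is from camera at the preset correlation and carries little weight, given the splits below. A higher share of macrophages may explain part, since the median fell from 0.35 to 0.19 (adjusted p = 0.00163) with a macrophage index, and libraries set apart by IgG are not excluded, because the median of 0.15 against untreated mice (adjusted p = 0.0174) met the bound written against that explanation but was lost without single libraries and had adjusted p = 0.792 with an estimated correlation. Of 100 splits of the compared libraries, the real one included, 9 had a camera p as small as the real one (6.76e-10; smallest other 2.98e-19), so chance cannot be excluded. PD-1 blockade, macrophage content, libraries set apart by IgG and chance thus all stay open.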

How the results depend on the processing

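Counts of calls kept within 1.5 times their main value in 101 alternatives and moved further in 42. The 47 list calls of the main setting kept direction and side of the threshold in 728 tests, lost it in 248 and turned in 9. Lists that passed only in an alternative setting were not counted here. Single genes kept direction and side in 1126, with 54 newly past the threshold and 64 no longer past it. The cause was not tested unless stated. Only the compared groups could not be taken for the gate comparison and the gate by D difference, which use all sorted groups.

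Anti-PD-1 against IgG had 0 calls, with 1 in DESeq2, 31 with no expression filter, 1 with letter and number as covariates, 1 in M libraries alone, and 0 to 2 with 1 library left out. Its interferon-gamma list had an adjusted p of 0.172 with an estimated correlation, 0.308 with fry and 0.701 in M alone. There MHC class II (0.566) and macrophage (0.191) turned. With the stromal index endothelium (0.782) and pericyte (0.664) turned, whose own genes make that index, and with 1 library left out erythroid ranged from 8.49e-07 to 0.931. Anti-PD-1 against untreated had 0 calls, with 2 in DESeq2, 13 with no filter, and 1 each without the letter, in M alone, with the macrophage index and with the stromal index. IgG against untreated had 0, with 2 in DESeq2, 27 with no filter and 0 to 1 with 1 library left out.

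D14 against D7 in CD45low had 9 calls, with 23 in DESeq2, 128 with no filter, 0 with limma on scaled values, 3 with recovered reads, 0 with the neutrophil index, and 0 to 34 with 1 library left out. With that index monocyte (0.971) and macrophage (0.0841) turned, and with 1 library left out macrophage ranged from 9.75e-04 to 0.773. In CD45high it had 1, with 15 in DESeq2, 0 with DESeq2 size factors, 0 with upper-quartile factors, 114 with no filter, 0 with the stricter filter, 13 with only the compared groups, 10 with limma, 6 with recovered reads and 0 to 13 with 1 library left out, and the neutrophil list turned with its own index (0.943). The gate by D difference had 0, with 31 with no filter. Between the gates counts stayed between 4344 and 5607.

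With the replicate number as a block, anti-PD-1 against IgG had 1 call, IgG against untreated 2, CD45low 15 and CD45high 4, and with the leading number as a block the gate by D difference had 1. Same-numbered samples correlated by -0.0397 to 0.164 in the choroid plexus. In the sorted cells the range was 0.0139 to 0.0608 for leading numbers and -0.00874 to 0.101 for replicate numbers. These correlations are small, so the numbers were not taken as pairing. For leading numbers all were above 0, with a median of 0.0448 against -0.00879 in other pairs, so pairing of the gates is not excluded. Same-numbered samples had a median of 0.0609 in the choroid plexus, against -0.0116 in other pairs. For replicate numbers in the sorted cells it was 0.0508, against -0.00879. Most same-numbered choroid plexus pairs also share the title letter, for which these correlations were not adjusted. Pairing by replicate number is thus not excluded either.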

Other observations

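The comparison of M with F choroid plexus libraries (n = 7 each), and the tests of it, were chosen after the data were seen. Every M title but that of untreated replicate 4 ends in the number 14, and every F title in a lower one. Apart from the genes of the Y chromosome, differences between M and F thus cannot be assigned to the letter or to the number. Of 9513 genes 24 were called between them, 9 higher in M, among them genes of the Y chromosome, and 15 higher in F, and 833 had an unadjusted p under 0.05. H2-Ab1, an MHC class II chain, had a log2 fold change of M against F of -1.03 ± 0.193 (adjusted p = 0.00923), Bst2, an interferon-induced antiviral gene, -1.27, A2m, a protease inhibitor, -2.11, and the collagen gene Col1a2 -0.67. Gpx3 had -1.41, Bgn -1.21, Socs2 -0.98, Ccnd2 -0.94, Pcsk2 -0.87, and the X-linked Ddx3x and Eif2s3x -0.56 and -0.64, while Trf, transferrin, had 0.65 and Slc35f1 1.13. These genes were chosen after their values were seen. Lists lower in M were interferon-gamma (adjusted p = 2.19e-09; adjusted p = 0.268 with an estimated correlation), MHC class II (2.32e-06; adjusted p = 0.268 with an estimated correlation), macrophage (1.67e-04; adjusted p = 0.410 with an estimated correlation), dendritic cell (0.0144; adjusted p = 0.268 with an estimated correlation) and type I interferon (0.0184; adjusted p = 0.410 with an estimated correlation). Lists higher in M were oligodendrocyte (0.00926; adjusted p = 0.245 with an estimated correlation), glucocorticoid response (0.0184; adjusted p = 0.410 with an estimated correlation) and oxidative phosphorylation (0.0404; adjusted p = 0.537 with an estimated correlation). The fibroblast list did not pass (0.445). For the macrophage and interferon-gamma lists the gap was largest in the anti-PD-1 group. The mean log2 CPM in M and F was 3.86 and 4.77 there for macrophage, 4.10 and 4.16 with IgG, and 4.21 and 4.51 in untreated mice. For interferon-gamma the M libraries of the anti-PD-1 group were at 4.89 and 5.25 and its F libraries at 5.38 to 5.93. With IgG these were 4.93 and 5.28, and 5.19 to 5.23. Untreated M libraries had a mean of 5.04 and the 1 untreated F library was at 5.44, so a gap was also seen without an antibody.

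The real counts of calls were set beside splits that mixed the libraries of the compared groups. For M against F 2 of 100 splits, the real one included, gave as many calls (real 24, highest other 38). The share lies under 0.05, but 1 other split called more genes and the comparison was chosen after the data were seen. The 24 calls include Ddx3y, Kdm5d and Uty, which were already seen to follow the letter. The splits thus cannot say whether chance explains the other calls. Between the gates 1 of 100 splits gave as many calls (real 4822, highest other 0), which argues against chance in how these libraries were grouped. The labels do not say whether they came from separate animals, so the splits cannot speak for animals. In the choroid plexus the real count was 0 in each comparison, which all 100 of 100 splits must reach, so that the splits say nothing about these counts; the highest others were 13 for anti-PD-1 against IgG, 7 for anti-PD-1 against untreated and 10 for IgG against untreated. For D14 against D7 in the CD45low gate only 10 splits exist, too few to decide, where 1 gave as many (real 9, highest other 1).

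The higher type I interferon list at D14 than at D7 in both gates could have technical or biological causes. A lower share of neutrophils at D14 was tested with a neutrophil index as a covariate. The lower of the 2 gate medians was then 0.77. The index had 1 slope for both gates, set mostly by the CD45low D7 libraries. Their neutrophil list level had an SD of 0.605, against 0.119 and 0.216 in the CD45high groups at D7 and D14. A lower neutrophil share in the CD45high gate is thus not decided by this test. A single library is argued against as to direction, since the lowest median with 1 left out was 0.56. Without either CD45high D14 library that group held 1 library, so its spread came from the other groups. With an estimated correlation the list did not pass in either gate (adjusted p = 0.331 in CD45low and adjusted p = 0.262 in CD45high). In the CD45low gate 10 splits are too few to decide, with 1 camera p as small as the real 5.35e-10 and the next at 3.69e-06. Time after treatment, the time of sorting and the animals behind each D label could not be told apart and stay open.

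Neutrophil transcripts higher at D7 than at D14 in the CD45low gate may be carried over from the CD45high population. Were the whole population carried over, neutrophil and monocyte genes should reach the same share of their CD45high level. The shares are medians over 11 neutrophil and 28 monocyte genes. These genes were picked in the same libraries for a level far higher in the CD45high gate, which by itself keeps both shares low. At D7 the neutrophil share was 0.826%, 0.810% and 2.11% and the monocyte share 1.54%, 1.02% and 4.48%, with ratios from 0.471 to 0.790. All ratios lie under the bound of 1.5 set for carry-over, but that bound has no lower limit and the shares were not the same. The choice of genes also held both shares low, so carry-over of the whole population stays open. At D14 the neutrophil shares were 0.812%, 0.589% and 1.03% and the monocyte shares 0.980%, 0.955% and 1.69%. Expression of these genes by cells of the microglia gate itself was not tested and stays open.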
